A study of Mus musculus with 40 samples.

How the data were processed

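Gene expression was measured by polyA RNA sequencing in brown adipose tissue (BAT) and inguinal white adipose tissue (iWAT) of male mice with or without whole-body deletion of MondoA, a glucose-responsive transcription factor encoded by Mlxip. Wild-type (WT) and knockout (KO) mice were placed at 8 weeks of age on chow or on a high-fat diet (HFD, 60% fat) for 16 weeks. There were 40 libraries, 4 in each of the 4 BAT groups and 6 in each of the 4 iWAT groups. Replicates 1 to 4, 5 to 8, 9 to 12 and 13 to 16 of BAT were WT chow, KO chow, WT HFD and KO HFD. In the same order, iWAT held replicates 1 to 6, 7 to 12, 13 to 18 and 19 to 24.

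Per the submitters' processing notes, reads were quantified against transcripts with Salmon 1.10.3 and the build was mm10. The annotation used for the Salmon index, and any trimming options, were not given in the sources used here. Each deposited file held, per the file headers, the estimated count of reads of each transcript (NumReads), the TPM, the length and the effective length. Estimated counts are the expected number of reads of a transcript after reads that match several transcripts are divided among them, so a gene with a near-identical copy elsewhere shares reads with that copy. Deposited TPM values are scaled to a fixed sum within a library, so they were used only to describe the Mlxip transcripts and not in tests.

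Of the 117135 transcripts in each file, 115973 matched a gene of the GENCODE M21 annotation (mm10), which gave 35523 genes, of which 24704 had a read in some library. The remaining 1162 transcripts took from 0.456% to 0.99% of the reads of a library and were left out of library sizes and gene tests. Changes of those transcripts were tested separately. Nuclear copies of mitochondrial genes took part of the reads, so levels of the mitochondrially encoded genes are less certain than those of other genes. Total reads per library ranged from 13.1e6 to 27.1e6 in BAT and from 18.8e6 to 26.4e6 in iWAT. Coordinates are from the same annotation and are counted from 1. Reads without molecular identifiers are not independent molecules, and the p-values given measure the spread between libraries.

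Transcript counts were summed to genes and rounded. Genes were tested in each tissue separately with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood fit of the 4 groups, robust dispersion, TMM normalization and the default low-count filter (minimum count 10, total 15, proportion 0.7), which left 13627 genes in BAT and 15078 in iWAT. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. The 5 comparisons per tissue were KO against WT on chow, KO against WT on HFD, HFD against chow in WT, HFD against chow in KO, and the genotype by diet interaction. The effect of deletion averaged over both diets was added after the results were seen. Differences of an effect between the tissues were tested in a fit of all 40 libraries. Means and standard deviations (SD) are in CPM, that is, read counts relative to library size scaled by the TMM factors, over the libraries of a group.

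The gene lists, 29 in number, the genes to be named and the comparisons were fixed before the data were examined. The lists were MondoA and ChREBP targets, brown and beige thermogenesis, calcium cycling, creatine cycling, triglyceride and fatty acid cycling, de novo lipogenesis, glycolysis and glucose uptake, pyruvate oxidation and TCA cycle, fatty acid oxidation, nuclear-encoded respiratory chain, mitochondrially encoded genes, branched-chain amino acid breakdown, cholesterol synthesis, glycogen metabolism, integrated stress response, circadian clock, immediate early genes, interferon response, cell division, extracellular matrix, and markers of adipocytes, adipocyte progenitors and fibroblasts, macrophages, T and B lymphocytes, endothelium, skeletal muscle, epithelium, Schwann cells and nerve, and blood. Each was tested as a set against all other genes with limma's camera (limma 3.58.1, preset correlation 0.01) and adjusted over the lists of a comparison. The same test was repeated with the correlation estimated from the libraries. The mean log2 CPM of a list per library (prior count 2) was compared by a two-sided exact permutation test over 70 assignments of 4 against 4 libraries or 924 of 6 against 6. The smallest p these can give is 0.0286 and 0.00216. The counts of called genes per list were also adjusted over the list alone.

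Genes were named by rule, and some genes that met it are not reported here. Mlxip, Mlx, Mlxipl, Txnip, Arrdc4, Ucp1 and Lep were named in every comparison. Among called genes with a mean of at least 5 CPM in a group and no overlap of the libraries, the 6 highest and 6 lowest log2 fold changes were named for KO against WT and the 4 highest and 4 lowest for HFD against chow, with predicted gene models passed over. The 2 called members of lowest p were named from the lists on MondoA and ChREBP targets, thermogenesis, calcium cycling, creatine cycling, triglyceride and fatty acid cycling, de novo lipogenesis and glycolysis. From any other list with at least 3 called members, 1 member of lowest p in the direction of the majority was named, and the 5 genes of lowest p were to be named for interactions and tissue differences if any were called. Members of a list named without having passed the test over all genes were chosen after their values were seen.

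Alternatives were RLE size factors, library totals only, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter at 1 CPM, transcript length offsets, a fit of only the 2 groups compared, exclusion of mitochondrially encoded genes, and each library left out in turn. After the data were seen, a marker score was added as a covariate (skeletal muscle in BAT, T and B lymphocyte in iWAT), and libraries with a score above 3 were left out, 7 in BAT and 6 in iWAT. The pipeline was tested on simulated counts in which 200 genes were changed. In the simulated BAT comparison of KO with WT on HFD, 21 of 67 genes changed 1.5-fold (31.3%), 59 of 67 changed 2-fold (88.1%) and 64 of 66 changed 4-fold (97%) were called among 13437 genes, with 5 unchanged genes called. In the simulated iWAT comparison the numbers were 30 of 67 (44.8%), 55 of 67 (82.1%) and 65 of 66 (98.5%) among 14947 genes, with 10 unchanged genes called. Replicates were checked for duplicated libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.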

Results

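RNA was profiled in BAT, the thermogenic depot, and iWAT, a subcutaneous depot in which beige adipocytes arise, of WT and MondoA KO male mice after 16 weeks on chow or HFD. BAT had 4 libraries and iWAT 6 libraries per genotype and diet. The design asks what loss of MondoA changes in each depot on each diet, what fat feeding changes in each genotype, and whether either effect differs between diets or depots. The lists on calcium, creatine and triglyceride cycling address the futile cycles named in the series title.

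Mlxip, the targeted gene (chromosome 5, 123394798 to 123457932), was measured in every library, and reads remained in the KO. In BAT on chow the libraries were at 42.3, 43.1, 38.9 and 40.5 CPM in WT and at 34.6, 27, 32.2 and 27.1 CPM in KO. On HFD the BAT libraries were at 41.5, 48.6, 37.2 and 42 CPM in WT and at 30.3, 33.1, 22.7 and 31.8 CPM in KO, so every KO library lay below every WT library in this tissue. In iWAT on chow Mlxip was at 59.5, 63.4, 46.3, 87.3, 86.7 and 60.4 CPM in WT and at 32.5, 43.9, 52.7, 42.4, 28.1 and 38.3 CPM in KO, where KO replicate 9 exceeded WT replicate 3. On HFD the iWAT libraries were at 49.7, 47.4, 46.1, 69.1, 40.7 and 60.5 CPM in WT and at 35.3, 26.3, 36.9, 29.1, 25.2 and 36 CPM in KO. The log2 fold change of KO against WT was -0.45 (SE 0.12) and -0.52 (SE 0.12) in BAT on chow and HFD, and -0.76 (SE 0.17) and -0.73 in iWAT. None of these passed the edgeR test over all genes (adjusted p = 1, 0.283, 0.825 and 0.481), whereas DESeq2 called the difference on HFD in BAT (adjusted p = 0.0257) and in iWAT (adjusted p = 0.0401), as did limma-voom in iWAT (-0.68, adjusted p = 0.0228). Averaged over both diets, a comparison added later, the iWAT difference was called (-0.75, SE 0.12, adjusted p = 0.00964).

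The full-length coding transcript Mlxip-201 (chromosome 5, 123394800 to 123457932) was at 2.08 ± 0.21 TPM (SD, n = 4) in KO and 3.31 ± 0.19 in WT BAT on chow. On HFD it was at 1.77 ± 0.46 and 3.71 ± 0.83. In iWAT (n = 6) it was at 3.49 ± 1.88 TPM in KO and 7.72 ± 2.84 in WT on chow, and at 2.38 ± 0.91 and 3.93 ± 1.63 on HFD. Mlxip-203, a transcript annotated as subject to nonsense-mediated decay that covers only the 3' part of the gene (chromosome 5, 123446039 to 123457929), was at 2.64 ± 0.44 TPM in KO and 2.90 ± 0.47 in WT BAT on chow. The HFD values of this transcript were 2.56 ± 0.63 and 2.84 ± 0.54. In iWAT it was at 4.12 ± 1.2 in KO and 4.79 ± 1.95 in WT on chow, and it was lower in KO on HFD (4.78 ± 0.89 against 8.46 ± 1.48). Which exons are deleted was not given in the sources used here, so gene-level reads do not measure how much intact message remained.

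**Figure D1:**
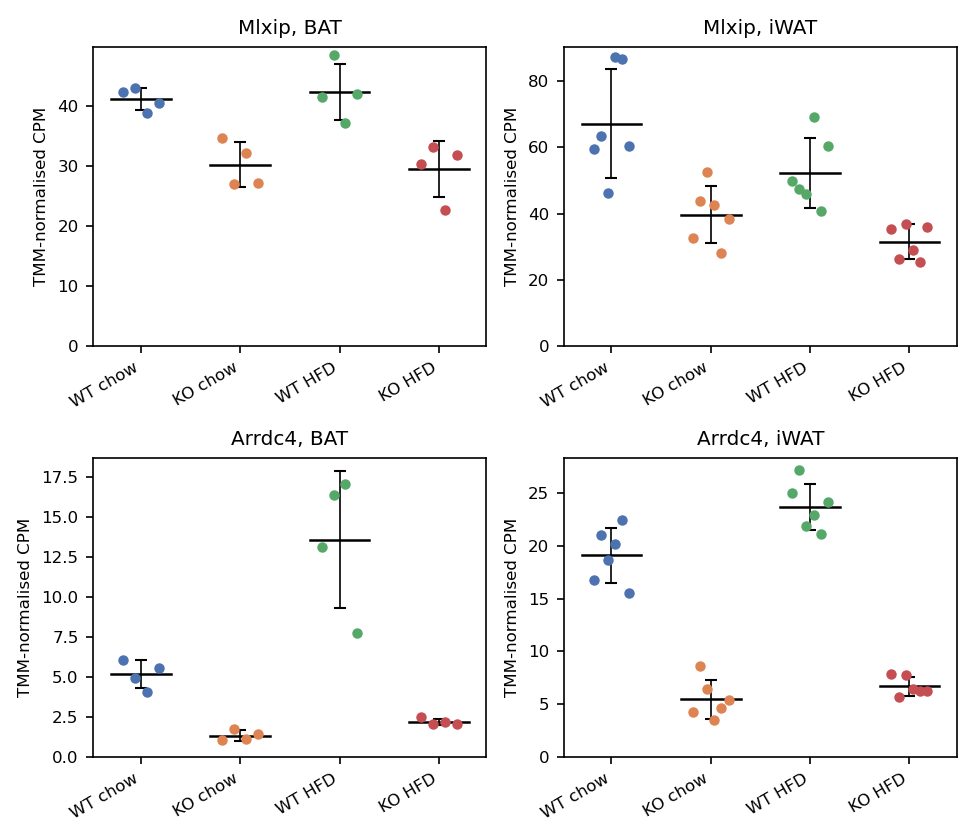
Levels of Mlxip and Arrdc4 (TMM-normalised CPM, vertical axis) in each library by group (horizontal axis), with 4 libraries per BAT group and 6 per iWAT group, the mean and the SD. Mlxip was lower in KO in every group pair, with the ranges of KO and WT libraries overlapping in iWAT on chow. Arrdc4 fell from 5.15 to 1.32 CPM in BAT on chow and from 23.7 to 6.68 CPM in iWAT on HFD.

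To ask what loss of MondoA changes in BAT on chow, KO and WT were compared (n = 4 each). Arrdc4 (chromosome 7, 68736995 to 68749241), an arrestin-domain gene and a direct MondoA target in other cells, was the only gene called among 13627. It fell by 1.95 on the log2 scale (SE 0.24, adjusted p = 0.00708), from 5.15 ± 0.867 CPM in WT to 1.32 ± 0.326 in KO. Txnip, the related and best known MondoA target, was at -0.21, and Mlx, the obligate partner of MondoA, was at 0.01. ChREBP itself (Mlxipl) was at -0.39 (SE 0.16), Ucp1, the uncoupling protein of brown fat, at -0.15, and Lep, encoding leptin, at -0.47, none past the test. Among the MondoA and ChREBP targets 1 of 11 members fell, also adjusted over the list alone, and the set was lower (median -0.10, adjusted p = 0.0132, 0.272 with an estimated correlation). Skeletal muscle markers were higher as a set (25 of 25 members positive, median 1.78, adjusted p = 0.0132, 0.978 with an estimated correlation). The libraries with muscle RNA were WT replicate 4 and KO replicates 7 and 8, at mean log2 CPM of 5.89, 7.82 and 3.21. Calcium cycling (median 0.82, adjusted p = 0.448) and creatine cycling (0.24, adjusted p = 0.349), lists that share abundant muscle genes, were not called. The nuclear-encoded respiratory chain was slightly lower (62 of 71 negative, median -0.05, adjusted p = 0.0209, and 0.978 as adjusted p with an estimated correlation). Smaller calls were made for blood markers (0.23, adjusted p = 0.0257 and 0.978), lymphocyte markers (3 members measured, 0.90, adjusted p = 0.0209 and 0.272) and epithelial markers (4 members, -0.45, adjusted p = 0.0353 and 0.413), where the latter value of each pair is the adjusted p with an estimated correlation. Library means of each of these sets overlapped between genotypes and none differed by the exact permutation test after adjustment (adjusted p = 0.918). Without the muscle-rich libraries the calls of skeletal muscle (adjusted p = 0.747), respiratory chain (0.0752), lymphocyte (0.193) and epithelial markers (0.381) ended. Length offsets ended those of the MondoA and ChREBP targets (0.0827), blood (0.0562) and epithelial markers (0.2). The call of Arrdc4 ended without KO replicate 5 (adjusted p = 0.0604) or KO replicate 7 (0.0649), and under limma-voom (0.331) and length offsets (0.48), with a fold change of -1.90 and -1.67. It also ended with only the 2 groups in the fit (-1.95, adjusted p = 0.0969) and without the muscle-rich libraries (-1.83, WT replicates 1 to 3, KO 5 and 6). At unadjusted p under 0.05 there were 383 genes, and DESeq2 called 2.

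On HFD the same comparison in BAT (n = 4 each) again called Arrdc4 alone, which fell by 2.63 (SE 0.24, adjusted p = 0.000113), from 13.6 ± 4.27 CPM in WT to 2.18 ± 0.197 in KO. Beyond this gene, markers of macrophages were lower and genes of mitochondrial fuel use were slightly higher in KO as sets. All 23 macrophage markers had negative fold changes (median -0.82, mean -1.01, adjusted p = 3.37e-19, 0.248 with an estimated correlation), with 0 members past the edgeR test over all genes and 13 lower adjusted over the list alone. Among them were Mpeg1, a pore-forming protein of phagocytes (-1.52, SE 0.27), and Ctss, a lysosomal protease (-1.63, SE 0.31). Others were Gpnmb (-2.29, SE 0.53) and Trem2 (-2.08, SE 0.59), lipid-associated macrophage genes, and Mmp12 (-2.39, SE 0.64). Their mean log2 CPM was 2.06 ± 0.25 in KO and 2.97 ± 0.6 in WT with no overlap of libraries, the smallest exact permutation p of the design (0.0286), which became 0.414 after adjustment. Interferon response genes were lower in 18 of 18 members (median -0.34, adjusted p = 3.11e-07, 0.338 with an estimated correlation). Also lower were 20 of 21 cell division genes (median -0.66, adjusted p = 7.52e-08 and 0.338), 23 of 26 extracellular matrix genes (-0.22, adjusted p = 5.01e-05 and 0.448) and 12 of 14 progenitor and fibroblast markers (-0.16, adjusted p = 0.00692 and 0.613), the latter of each pair with an estimated correlation. Without the muscle-rich libraries the call of cell division ended (adjusted p = 0.144), and its interaction with diet turned in direction (from 8.77e-05 to 0.724).

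In the same BAT comparison on HFD, 69 of 71 respiratory chain genes had positive fold changes, of small size (median 0.11, adjusted p = 3.97e-06, 0.613 with an estimated correlation). Their library means were 8.53 ± 0.04 in KO and 8.41 ± 0.07 in WT (log2 CPM, n = 4) without overlap (exact permutation p = 0.0286, adjusted 0.414). Fatty acid oxidation was positive in 24 of 24 members (median 0.12, adjusted p = 0.000574), pyruvate oxidation and TCA cycle in 24 of 25 (0.13, adjusted p = 0.00796) and brown and beige thermogenesis in 19 of 26 (0.11, adjusted p = 0.0364), each with an adjusted p = 0.613 with an estimated correlation. Mitochondrially encoded genes were positive in 12 of 13 (0.14, adjusted p = 0.00223, 0.467 with an estimated correlation), 3 of them past the test over the list alone. Without KO replicate 13 the calls of fatty acid oxidation (adjusted p = 0.105), mitochondrially encoded genes (0.055), TCA cycle, thermogenesis and progenitor markers ended. Ucp1 was at 0.04 and Lep at -1.18 (SE 0.77), with 78.6 ± 53 CPM in KO and 177 ± 41.8 in WT, neither past the test. Txnip (0.00), Mlxipl (-0.21) and Mlx (-0.26) did not pass either. Of the MondoA and ChREBP targets 1 of 11 fell (median -0.05, adjusted p = 0.0202, 0.338 with an estimated correlation). Immediate early genes (median -0.59, adjusted p = 0.005), endothelial markers (-0.14, adjusted p = 0.00436) and blood markers (-0.11, adjusted p = 0.0364) were lower, each with an adjusted p = 0.613 with an estimated correlation. So were cholesterol synthesis (-0.16, adjusted p = 0.0491 and 0.614) and the 3 lymphocyte markers (-0.71, adjusted p = 0.0189 and 0.338, the latter with an estimated correlation). Skeletal muscle markers were positive in 25 of 25 members (median 1.61, adjusted p = 0.102), with high scores in WT replicates 9 and 10 (6.41 and 8.84) and KO replicates 14 and 16 (9.54 and 9.92). Without the muscle-rich libraries they turned to lower in KO (adjusted p = 1.42e-10). The calls of thermogenesis (0.251), mitochondrially encoded genes (0.0728), MondoA and ChREBP targets (0.0627), immediate early genes (0.0627), endothelial (0.115), blood (0.813) and lymphocyte markers (0.544) then ended, and that of cholesterol synthesis ended with the muscle score as a covariate (0.0798). Without the muscle-rich libraries, with WT replicates 11 and 12 against KO 13 and 15, edgeR called 0 genes (Arrdc4 -2.43, adjusted p = 0.556). DESeq2 called 44 genes in all libraries, 13 higher and 31 lower. At unadjusted p under 0.05 there were 1060 genes.

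**Figure D2:**
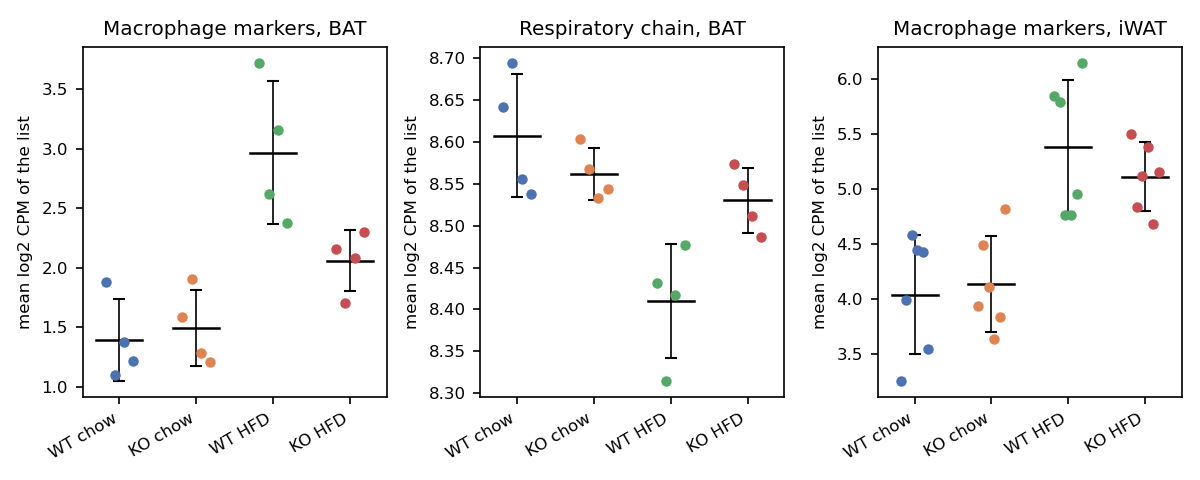
Mean log2 CPM (vertical axis) of macrophage markers in BAT, the nuclear-encoded respiratory chain in BAT and macrophage markers in iWAT, in each library by group, with the mean and the SD (n = 4 in BAT, n = 6 in iWAT). On HFD the macrophage markers of BAT were at 2.06 in KO and 2.97 in WT, and the respiratory chain at 8.53 and 8.41.

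Whether the effect of deletion in BAT differed between diets was tested by the genotype by diet interaction. edgeR, DESeq2 and limma-voom each called 0 genes, with 541 genes at unadjusted p under 0.05 in edgeR. The interaction of Arrdc4 was -0.68 (SE 0.33, adjusted p = 1). Of the sets, macrophage markers had the lowest p (22 of 23 negative, median -1.03, adjusted p = 9.94e-17, 0.173 with an estimated correlation). KO thus stood lower against WT on HFD than on chow. Interferon response genes (18 of 18 negative, median -0.61, adjusted p = 3.28e-09 and 0.336) and the respiratory chain (70 of 71 positive, median 0.17, adjusted p = 4.64e-09 and 0.575) also differed between diets, the latter of each pair with an estimated correlation. Glycolysis and glucose uptake was positive in 17 of 20 members (median 0.25, adjusted p = 0.00658, 0.589 with an estimated correlation). Calcium cycling (0.09, adjusted p = 0.976, with a mean of -0.16), creatine cycling (-0.09, adjusted p = 0.614) and triglyceride and fatty acid cycling (0.08, adjusted p = 0.535) showed no difference past the test.

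To describe what HFD changed in BAT of WT mice, HFD and chow were compared (n = 4 each). Macrophage, cell division and endothelial genes rose and lipogenic genes fell, among 2229 called genes (1182 higher, 1047 lower; 1629 higher and 447 lower when scaled by library totals alone). The highest fold change was that of Amd1, of polyamine synthesis (7.24, SE 2.27, adjusted p = 0.0474), a call that 10 of the 16 single libraries left out ended (adjusted p up to 0.118), as did limma-voom (0.224), length offsets (0.0997) and no low-count filter (0.0757). Next were Mmp12, the macrophage elastase (6.95, SE 0.91, chromosome 9, 7344381 to 7369499), Prnd, encoding the prion-like protein doppel (5.70, SE 1.06), and Gdf15, a secreted stress-induced factor (4.92, SE 1.0), with adjusted p from 0.000558 to 0.00581. Lep rose by 3.54 (SE 0.84, adjusted p = 0.0151), from 15.3 ± 15.2 to 177 ± 41.8 CPM. Of 23 macrophage markers 16 rose (18 adjusted over the list alone; median 1.36, set adjusted p = 5.21e-13, 0.236 with an estimated correlation). Cell division genes rose in 15 of 21 (17 over the list alone; median 1.72, set adjusted p = 4.31e-12, 0.236 with an estimated correlation), such as the proliferation marker Mki67 (2.58, SE 0.41). Endothelial markers rose in 8 of 14 (10 over the list alone; 0.55, set adjusted p = 3.03e-06, 0.334 with an estimated correlation), among them Pecam1 (0.74, SE 0.13). Interferon genes rose in 8 of 18 (11 over the list alone; 0.67, set adjusted p = 1.23e-05, 0.435 with an estimated correlation; Ifit2 1.2, SE 0.25). Extracellular matrix genes rose in 6 of 26 (8 over the list alone; 0.41, set adjusted p = 8.32e-05, 0.435 with an estimated correlation; Sparc 0.78, SE 0.11).

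In the same comparison de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, fell in 10 of 20 members (15 adjusted over the list alone; median -0.81, set adjusted p = 2.89e-09, 0.334 with an estimated correlation). Elovl6, a fatty acid elongase, fell by 1.01 (SE 0.18) and Acacb, an acetyl-CoA carboxylase, by 0.69 (SE 0.12). Triglyceride and fatty acid cycling fell in 8 of 27 (9 over the list alone; -0.23, set adjusted p = 0.000748, 0.448 with an estimated correlation), including Acsl5, an acyl-CoA synthetase (-1.1, SE 0.22), and Abhd5, the coactivator of triglyceride lipase (-0.57, SE 0.11). The respiratory chain fell in 28 of 71 (39 over the list alone; -0.22, set adjusted p = 1.7e-07, 0.448 with an estimated correlation; Cox7b -0.44, SE 0.06). Pyruvate oxidation and TCA cycle fell in 9 of 25 with 1 rise (12 and 1 over the list alone; -0.23, set adjusted p = 0.00205, 0.449 with an estimated correlation). Pcx, pyruvate carboxylase, was at -0.93 (SE 0.15). Branched-chain amino acid breakdown fell in 8 of 21 (10 over the list alone; -0.31, set adjusted p = 0.000742, 0.448 with an estimated correlation; Hsd17b10 -0.82, SE 0.14). Cholesterol synthesis fell in 4 of 21 (4 over the list alone; -0.38, set adjusted p = 0.00225, 0.448 with an estimated correlation; Idi1 -0.83, SE 0.18). The lowest fold changes were those of the cytochromes P450 Cyp1a1 (-3.65, SE 0.97) and Cyp2e1 (-2.52, SE 0.58), of Mmd2 (-2.60, SE 0.51) and of Vat1l (-2.30, SE 0.37). The adipocyte product Cfd, adipsin, fell by 2.12 (SE 0.46) and the potassium channel Kcnk3 by 1.01 (SE 0.18), while Fabp3, a fatty acid carrier, rose by 1.30 (SE 0.21).

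Of the fixed genes, Arrdc4 rose with HFD in WT BAT (1.40, SE 0.22, adjusted p = 0.00124). With length offsets it was at 0.78 and not called (adjusted p = 0.0939), nor was it without the muscle-rich libraries (1.32, adjusted p = 0.0559). Ucp1 (0.23), Mlxip (0.04), Mlx (-0.23), Txnip (-0.35) and Mlxipl (-0.42) did not pass the test. Calcium cycling genes were higher as a set (17 of 18 positive, median 2.16, adjusted p = 0.00648, 0.448 with an estimated correlation) with 1 called member, Ryr2, the cardiac-type ryanodine receptor (2.65, SE 0.39, adjusted p = 0.000971). Skeletal muscle markers moved with that list (25 of 25 positive, median 2.93, adjusted p = 0.00637, 0.636 with an estimated correlation, 0 members called by edgeR). Muscle scores were 5.89 in 1 chow library and 6.41, 8.84 and 2.29 in 3 HFD libraries. Progenitor and fibroblast markers rose in 4 of 14 (5 over the list alone; 0.38, adjusted p = 0.000912, 0.448 with an estimated correlation; Icam1 1.26, SE 0.15). Immediate early genes rose in 3 of 18 with 1 fall (0.82, adjusted p = 0.0026, 0.456 with an estimated correlation; Jund 0.96, SE 0.22) and blood markers rose in 2 of 11 (0.38, adjusted p = 0.0144, 0.448 with an estimated correlation). Glycogen metabolism (3 of 18 fell, median -0.12, adjusted p = 0.136; Pygl -0.87, SE 0.23) and glycolysis (1 rose and 2 fell of 20, -0.08, adjusted p = 0.292, with a mean of 0.04; Hk1 0.68, SE 0.17, Pfkfb3 -0.78, SE 0.18) were not called as sets. Nor were adipocyte markers (4 rose and 5 fell of 19, -0.09, adjusted p = 0.531, with a mean of 0.23) and Schwann cell markers (1 of 11 rose, 0.02, adjusted p = 0.531). Eci1, of fatty acid oxidation, fell by 0.40 (SE 0.11, adjusted p = 0.0291). Leaving out any of 6 libraries ended that call (adjusted p up to 0.0876). The count of called genes was 1407 without WT chow replicate 2, 1437 without 3, 1458 without 4 and 1238 without WT HFD replicate 11. It was 668 without the muscle-rich libraries, where the set calls of cholesterol synthesis (adjusted p = 0.14) and blood markers (0.0599) ended. With the muscle score as a covariate that of calcium cycling (0.212) ended. Of the 32 named calls 16 were lost without the muscle-rich libraries, where WT replicates 1 to 3 were compared with 11 and 12. These were Arrdc4, Lep, Amd1, Prnd, Cfd, Cyp2e1, Mmd2, Mki67, Ifit2, Idi1, Hsd17b10, Hk1, Pfkfb3, Pygl, Abhd5 and Eci1 (adjusted p from 0.0559 to 0.345). With the muscle score as a covariate only Eci1 was lost (0.0521). With only the 2 groups in the fit Cyp1a1 (0.077) and Cyp2e1 (0.078) were not called.

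In KO BAT (n = 4 each) HFD changed 1166 genes, 588 higher and 578 lower, with lipogenic genes again falling. De novo lipogenesis fell in 12 of 20 members (15 adjusted over the list alone; median -0.97, set adjusted p = 1.57e-11, 0.722 with an estimated correlation). Slc25a1, the mitochondrial citrate carrier, was at -1.34 (SE 0.24) and the elongase Elovl5 at -1.14 (SE 0.17). The highest fold changes were those of Ryr2 (3.16, SE 0.39), the channel gene Hcn2 (2.59, SE 0.67), Npr3, the natriuretic peptide clearance receptor (2.39, SE 0.58), and Slc6a13, a GABA transporter (2.29, SE 0.60), with adjusted p from 0.000732 to 0.0326. The lowest were those of Cyp1a1 (-4.70, SE 1.06), Cyp2e1 (-2.90, SE 0.59), Gpx8 (-2.27, SE 0.24) and Hcar1, the lactate receptor (-2.26, SE 0.34). Macrophage markers rose in 1 of 23 (median 0.39, set adjusted p = 0.0189, 0.808 with an estimated correlation). Cell division genes rose in 4 of 21 (8 over the list alone; 0.97, set adjusted p = 1.39e-06, 0.722 with an estimated correlation). Endothelial markers rose in 2 of 14 (4 over the list alone; 0.35, set adjusted p = 3.05e-05, 0.722 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 13 (5 over the list alone; 0.23, set adjusted p = 0.0125, 0.722 with an estimated correlation). Cholesterol synthesis fell in 4 of 21 (8 over the list alone; -0.48, set adjusted p = 0.000197, 0.722 with an estimated correlation), with Fdft1, squalene synthase, at -1.90 (SE 0.34).

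Triglyceride and fatty acid cycling in KO BAT fell with HFD in 4 of 27 members (8 over the list alone; -0.20, set adjusted p = 0.00162, 0.729 with an estimated correlation). Members that fell included Acsl5 (-1.02, SE 0.22) and Abhd5 (-0.48, SE 0.11). Branched-chain amino acid breakdown fell in 8 of 21 (11 over the list alone; -0.23, set adjusted p = 0.000606, 0.729 with an estimated correlation), such as Acadsb (-0.47, SE 0.10). The respiratory chain was not called in KO (4 of 71 fell, median -0.04, adjusted p = 0.172). Calcium cycling (18 of 18 positive, median 2.39, adjusted p = 0.0056, 0.722 with an estimated correlation) again moved with skeletal muscle markers (25 of 25 positive, 2.76, adjusted p = 0.02, 0.842 with an estimated correlation). The adipokine gene Adipoq fell by 0.71 (SE 0.14), Kcnk3 by 0.82 (SE 0.18), Pcx by 0.92 (SE 0.15) and Mlx by 0.50 (SE 0.12, adjusted p = 0.0197), while Fabp3 rose by 1.05 (SE 0.21). Lep (2.83, SE 0.82, adjusted p = 0.0522), Arrdc4 (0.72, SE 0.24, adjusted p = 0.0754) and Ucp1 (0.43, SE 0.16, adjusted p = 0.114) did not pass, though DESeq2 (0.00325), limma-voom (0.00492) and the filter at 1 CPM (0.0488) called Lep. The calls of Hcn2, Npr3, Slc6a13 and Mlx ended without 6, 4, 5 and 4 of the 16 libraries in turn, with adjusted p up to 0.0927, 0.0729, 0.0913 and 0.0588. The count of called genes was 590 without KO chow replicate 5, 606 without KO chow replicate 8, 577 without KO HFD replicate 16 and 100 without the muscle-rich libraries. Without the latter the set calls of macrophage markers (adjusted p = 0.415), branched-chain amino acid breakdown (0.102), triglyceride and fatty acid cycling (0.0688) and skeletal muscle (0.102) ended. With the muscle score as a covariate calcium cycling was not called (0.124). Of the 25 named calls 23, all but Cyp1a1 and Elovl5, were lost without the muscle-rich libraries (adjusted p from 0.0504 to 0.399). That fit compared only KO replicates 5 and 6 with 13 and 15. With the muscle score as a covariate all 31 named results kept their direction and side of the threshold. With only the 2 groups in the fit Npr3 (0.0701) and Slc6a13 (0.109) were not called, and without a low-count filter Hcn2 (0.0559) and Slc6a13 (0.059) were not. WT and KO shared 412 rises (51 expected if independent) and 387 falls (44.41 expected). Their log2 fold changes correlated across genes (r = 0.785).

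In iWAT on chow (n = 6 each) Arrdc4 was the gene called among 15078. It fell by 1.80 (SE 0.16, adjusted p = 2.11e-06), from 19.1 ± 2.62 CPM in WT to 5.45 ± 1.85 in KO. Txnip (-0.07), Mlx (-0.07), Mlxipl (0.28), Ucp1 (-0.41) and Lep (1.06) did not pass. Endothelial markers were higher in KO as a set (13 of 14 positive, median 0.38, adjusted p = 3.62e-06, 0.811 with an estimated correlation). Also higher were blood markers (10 of 11 positive, 0.39, adjusted p = 0.000238 and 0.811), circadian clock genes (13 of 17, 0.29, adjusted p = 0.00932 and 0.811), adipocyte markers (15 of 19, 0.12, adjusted p = 0.0283 and 0.999) and immediate early genes (13 of 18, 0.23, adjusted p = 0.0427 and 0.999), the latter of each pair with an estimated correlation. Lymphocyte markers were lower (20 of 20 negative, median -0.93, adjusted p = 0.00121, 0.999 with an estimated correlation). Their mean log2 CPM was 2.57 ± 2.24 in KO and 3.37 ± 2.94 in WT, with high scores in WT replicates 4, 5 and 6 and KO replicates 9 and 12. Progenitor and fibroblast markers were lower as well (11 of 14, -0.22, adjusted p = 0.0183, 0.999 with an estimated correlation). Without the lymphocyte-rich libraries the lymphocyte markers turned to higher in KO (adjusted p = 0.000583). Blood markers turned as well without those libraries (0.6), and the calls of endothelial markers (0.185), circadian clock (0.271), immediate early genes (0.271) and adipocyte markers (0.728) ended. Library means overlapped for all 7 called sets, and none passed the exact permutation test after adjustment (adjusted p = 1). The number of called sets was 12 without WT replicate 1, 19 without KO replicate 8 and 15 without KO replicate 11. At unadjusted p under 0.05 there were 423 genes.

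On HFD in iWAT (n = 6 each) Arrdc4 fell by 1.83 (SE 0.16, adjusted p = 1.5e-06), from 23.7 ± 2.2 to 6.68 ± 0.91 CPM, and was again the gene called. Txnip (-0.06), Mlx (-0.17), Mlxipl (0.18), Ucp1 (0.99) and Lep (0.20) did not pass. The MondoA and ChREBP targets were lower as a set (adjusted p = 0.00892, 0.501 with an estimated correlation), with 1 of 12 past the test, a median of -0.03 and a mean of -0.18. Their library means differed (6.38 ± 0.1 in KO, 6.58 ± 0.08 in WT, exact permutation p = 0.00433, adjusted 0.0419). Blood markers were higher in KO (9 of 11 positive, 7 adjusted over the list alone, 0 over all genes in edgeR; median 0.89, adjusted p = 2.71e-09, 0.175 with an estimated correlation). Library means did not overlap (4.86 ± 0.31 against 4.21 ± 0.18, exact permutation p = 0.00216, adjusted 0.0313). Members were the globin Hba-a1 (0.89, SE 0.31), the heme synthesis enzyme Alas2 (0.91, SE 0.31) and the red-cell anion exchanger Slc4a1 (1.36, SE 0.36). Lymphocyte markers were lower in KO (20 of 20 negative, 18 adjusted over the list alone, 0 over all genes in edgeR; median -3.83, adjusted p = 5.33e-08, 0.842 with an estimated correlation). Library means were 0.36 ± 0.21 against 2.03 ± 2.19 (exact permutation p = 0.00216, adjusted 0.0313), where WT replicate 16 was at 6.43.

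Genes of branched-chain amino acid breakdown were higher in KO iWAT on HFD in 21 of 21 members, by small amounts (median 0.17, adjusted p = 0.000213, 0.842 with an estimated correlation). Their library means differed before adjustment (exact permutation p = 0.0411, adjusted 0.298). Cholesterol synthesis was lower in 21 of 22 (median -0.26, adjusted p = 0.000604), with Insig1 at -0.77 (SE 0.34) and Hmgcs1 at -0.48 (SE 0.25). Cell division was lower in 22 of 22 (-0.42, adjusted p = 0.00156). Adipocyte markers were higher in 16 of 19 (0.25, adjusted p = 0.00056; Pnpla2, the triglyceride lipase, 0.47, SE 0.22) and extracellular matrix in 19 of 26 (0.23, adjusted p = 0.0214). So were triglyceride and fatty acid cycling in 20 of 27 (0.10, adjusted p = 0.0234) and the respiratory chain in 55 of 71 (0.08, adjusted p = 0.0315). Macrophage markers (22 of 24 negative, -0.29, adjusted p = 0.0146) and interferon response genes (18 of 19 negative, -0.16, adjusted p = 0.0234) were lower. Each of these sets had an adjusted p = 0.842 with an estimated correlation. With the lymphocyte score as a covariate cell division (adjusted p = 0.902), triglyceride and fatty acid cycling (0.958) and the respiratory chain (0.958) turned in direction. The calls of branched-chain amino acid breakdown (0.0839), adipocyte markers (0.127), extracellular matrix (0.807), interferon response (0.507) and epithelial markers (0.065) ended. Brown and beige thermogenesis (-0.04, adjusted p = 0.79), calcium cycling (-0.01, adjusted p = 0.412), creatine cycling (0.25, adjusted p = 0.66) and de novo lipogenesis (0.15, adjusted p = 0.0502) were not called. Epithelial markers were higher in 7 of 7 members (median 2.69, 7 adjusted over the list alone, adjusted p = 0.0118, 0.842 with an estimated correlation). This rested on KO replicate 20, at 5.42 against 0.258 in the next library. Without it the adjusted p was 0.693 and 7 sets were called in place of 13. At unadjusted p under 0.05 there were 1158 genes, and DESeq2 called 17 genes and limma-voom 24.

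**Figure D3:**
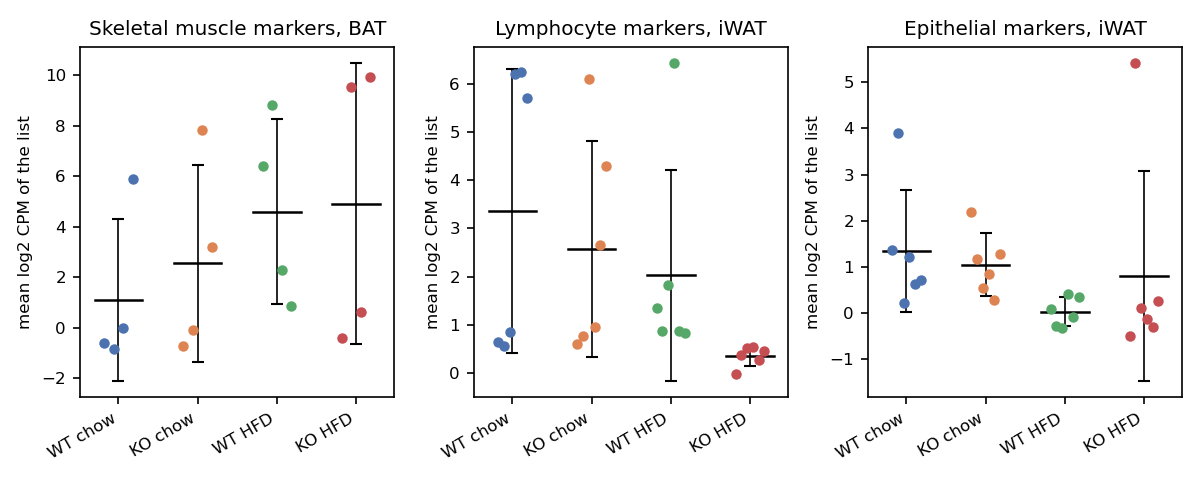
Mean log2 CPM (vertical axis) of skeletal muscle markers in BAT, T and B lymphocyte markers in iWAT and epithelial markers in iWAT, in each library by group, with the mean and the SD (n = 4 in BAT, n = 6 in iWAT). Single libraries stood far above the others of their group, such as WT chow replicate 4 for muscle (5.89), WT HFD replicate 16 for lymphocytes (6.43) and KO HFD replicate 20 for epithelium (5.42).

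The interaction in iWAT held 0 called genes in edgeR, DESeq2 and limma-voom, with 359 at unadjusted p under 0.05 in edgeR, and Arrdc4 was at -0.02. The sets of lowest p were epithelial markers (7 of 7 positive, median 3.37, adjusted p = 0.000675), which ended without KO HFD replicate 20 (adjusted p = 0.518), and branched-chain amino acid breakdown (19 of 21 positive, 0.18, adjusted p = 0.000728). The latter ended without WT chow replicate 1 or KO chow replicate 8 (up to 0.166). Lymphocyte (-2.81, adjusted p = 0.00364), macrophage (-0.38, adjusted p = 0.00798) and cell division sets (-0.38, adjusted p = 0.00529) were more negative on HFD than on chow. With the lymphocyte score as a covariate the call of cell division (0.166) ended. Every iWAT interaction set called had an adjusted p = 0.885 with an estimated correlation. The number of called sets was 11, and it was 5 without WT chow replicate 1, 6 without WT chow replicate 3 and 18 without WT chow replicate 4.

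In WT iWAT (n = 6 each) HFD changed 4625 genes, 2455 higher and 2170 lower (3455 and 1125 when scaled by library totals alone). Macrophage, matrix and cell division genes rose, and lipogenic, thermogenic and mitochondrial genes fell. The highest fold changes were those of Itgad, a macrophage integrin (5.65, SE 0.79), Mmp12 (5.31, SE 0.78), Lipf, a lipase (5.27, SE 0.80), and Tph2, a tryptophan hydroxylase (4.86, SE 0.75), with adjusted p from 0.00022 to 0.000263. Lep rose by 3.22 (SE 0.58, adjusted p = 0.000631), from 347 ± 182 to 3240 ± 969 CPM. Extracellular matrix genes rose in 18 of 26 (21 adjusted over the list alone; median 1.02, set adjusted p = 4.75e-10, 0.402 with an estimated correlation; Col4a2 1.57, SE 0.27). Macrophage markers rose in 11 of 24 (11 over the list alone; 0.74, set adjusted p = 5.2e-07, 0.407 with an estimated correlation). Cell division genes rose in 14 of 22 (17 over the list alone; 1.19, set adjusted p = 2.64e-07, 0.46 with an estimated correlation; Ube2c 1.41, SE 0.26). Endothelial markers rose in 9 of 14 (10 over the list alone; 0.83, set adjusted p = 1.35e-05, 0.46 with an estimated correlation; Esam 0.98, SE 0.20). The integrated stress response rose in 9 of 20 with 1 fall (9 and 1 over the list alone; 0.33, set adjusted p = 0.00662, 0.402 with an estimated correlation; Ddit3 0.76, SE 0.15).

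De novo lipogenesis in WT iWAT fell in 15 of 20 members (15 over the list alone; median -1.50, set adjusted p = 5.71e-10, 0.402 with an estimated correlation). Elovl6 was at -4.34 (SE 0.67), Acaca, the cytosolic acetyl-CoA carboxylase, at -3.81 (SE 0.52) and Acacb at -2.88 (SE 0.44). Slc2a5, the fructose transporter, fell by 5.74 (SE 0.88) and Ttc25 by 3.65 (SE 0.76). Ucp1 fell by 5.80 (SE 1.59, adjusted p = 0.00916), from 117 ± 179 to 2.09 ± 0.804 CPM, a call that limma-voom did not make (-3.74, adjusted p = 0.106). Thermogenesis genes fell in 15 of 24 (16 over the list alone; -1.28, set adjusted p = 1.18e-06), among them Ppara (-2.14, SE 0.38) and Ebf2 (-0.88, SE 0.15). The respiratory chain fell in 47 of 71 (57 over the list alone; -0.65, set adjusted p = 1.44e-11; Ndufs1 -1.13, SE 0.23). Pyruvate oxidation and TCA cycle fell in 17 of 25 (23 over the list alone; -0.88, set adjusted p = 6.54e-09; Suclg2 -1.05, SE 0.17) and fatty acid oxidation fell in 14 of 24 with 1 rise (20 and 1 over the list alone; -0.70, set adjusted p = 2.89e-06; Crat -1.17, SE 0.23). Mitochondrially encoded genes fell in 9 of 13 (12 over the list alone; -1.1, set adjusted p = 1.09e-05; mt-Nd5 -1.1, SE 0.24). These 4 sets and thermogenesis each had an adjusted p = 0.46 with an estimated correlation. The library means of each differed by the exact permutation test after adjustment (adjusted p from 0.0104 to 0.0179). Branched-chain amino acid breakdown fell in 19 of 21 (19 over the list alone; -0.74, set adjusted p = 2.19e-11; Aldh6a1 -1.19, SE 0.17). Glycogen metabolism fell in 11 of 17 with 1 rise (12 and 1 over the list alone; -0.86, set adjusted p = 9.73e-06; Gys1, glycogen synthase, -1.2, SE 0.21), each set with an adjusted p = 0.402 with an estimated correlation.

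Glycolysis and glucose uptake in WT iWAT fell with HFD in 8 of 20 members with 1 rise (median -0.62, set adjusted p = 0.00727, 0.46 with an estimated correlation). The insulin-regulated glucose transporter Slc2a4 was at -1.04 (SE 0.25), Pfkm at -0.90 (SE 0.25) and Hk2 at -0.78 (SE 0.23). Triglyceride and fatty acid cycling fell in 10 of 27 and rose in 2 (-0.41, set adjusted p = 0.00998, 0.527 with an estimated correlation). Pck1, of glyceroneogenesis, was at -2.35 (SE 0.42) and the phosphatidate phosphatase Lpin1 at -1.15 (SE 0.18). Skeletal muscle markers fell in 12 of 22 (16 over the list alone; -3.04, set adjusted p = 0.00249, 0.527 with an estimated correlation; Myh1 -4.60, SE 1.19). Schwann cell markers fell in 3 of 12 (-0.63, set adjusted p = 0.0318, 0.527 with an estimated correlation; Cdh19 -1.24, SE 0.34). Creatine cycling rose in 3 of 8 and fell in 2 (median 0.06, mean -0.93, adjusted p = 0.409; the creatine transporter Slc6a8 0.71, SE 0.19, and the synthesis enzyme Gamt 0.71, SE 0.17). Calcium cycling rose in 4 of 16 and fell in 2 (median 0.16, mean -0.20, adjusted p = 0.249; Ryr2 2.79, SE 0.43, and Jph1 1.02, SE 0.28). Neither was called as a set, nor were the MondoA and ChREBP targets (5 of 12 fell, -0.31, adjusted p = 0.133). Cfd fell by 3.10 (SE 0.53), Mlxipl by 1.08 (SE 0.33, adjusted p = 0.0175) and Mlx by 0.46 (SE 0.14, adjusted p = 0.0138). Hsd17b7, of cholesterol synthesis, rose by 0.89 (SE 0.26), Btg2 by 0.59 (SE 0.19), and Tkfc, a fructose-pathway kinase, fell by 0.35 (SE 0.11). Mlxip (-0.36, adjusted p = 0.103), Txnip (-0.27) and Arrdc4 (0.31, adjusted p = 0.138) did not pass. limma-voom called Mlxip (0.0331), and limma-voom (0.0118), length offsets (0.021) and the fit of only the 2 groups (0.0344) called Arrdc4. Myh1 was not called by limma-voom (0.227), Hk2 with length offsets (0.147) or Hsd17b7 without the lymphocyte-rich libraries (0.0862). The calls of Mlxipl, Tkfc and Btg2 ended without WT chow replicate 3 (adjusted p = 0.0547), WT chow replicate 1 (0.0503), and either WT chow replicate 1 or WT HFD replicate 14 (up to 0.053). Scaling by library totals ended those of Tkfc (0.171) and Mlx (0.06).

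In KO iWAT (n = 6 each) HFD changed 3894 genes, 1830 higher and 2064 lower (2392 and 1120 when scaled by library totals alone). Among the highest fold changes were those of Itgad (3.56, SE 0.70), Trem2 (2.36, SE 0.58) and Ccn1, a matricellular protein (2.13, SE 0.42). Lep rose by 2.36 (SE 0.56, adjusted p = 0.00642). Extracellular matrix genes rose in 19 of 26 (21 adjusted over the list alone; median 1.05, set adjusted p = 2.87e-15, 0.248 with an estimated correlation; Col6a2 1.57, SE 0.25). Macrophage markers rose in 9 of 24 with 1 fall (13 and 2 over the list alone; 0.64, set adjusted p = 1.5e-05; Lgals3 1.49, SE 0.32) and cell division genes rose in 6 of 22 (8 over the list alone; 0.78, set adjusted p = 4.26e-05). De novo lipogenesis fell in 16 of 20 (16 over the list alone; -1.37, set adjusted p = 1.59e-09), with Elovl6 at -4.47 (SE 0.67) and Acaca at -3.20 (SE 0.51). Thermogenesis fell in 15 of 24 (17 over the list alone; -1.64, set adjusted p = 5.27e-07), with the coactivators Ppargc1a at -1.66 (SE 0.30) and Ppargc1b at -1.60 (SE 0.32). Mitochondrially encoded genes fell in 13 of 13 (13 over the list alone; -1.24, set adjusted p = 8.02e-08; mt-Atp6 -1.53, SE 0.36). Macrophage markers, lipogenesis, thermogenesis and mitochondrially encoded genes each had an adjusted p = 0.435 with an estimated correlation, and cell division 0.498. The respiratory chain fell in 35 of 71 with 1 rise (-0.64, set adjusted p = 1.38e-10, 0.498 with an estimated correlation; Ndufs1 -1, SE 0.23). The TCA cycle fell in 19 of 25 (-0.87, set adjusted p = 1.14e-08, 0.435 with an estimated correlation). Branched-chain amino acid breakdown fell in 16 of 21 with 1 rise (-0.56, set adjusted p = 7.55e-08, 0.435 with an estimated correlation; Aldh6a1 -0.89, SE 0.17).

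The lowest fold changes of HFD in KO iWAT were those of Glycam1, of high endothelial venules, at -8.78 (SE 2.39, adjusted p = 0.0123), Cr2 at -6.28 (SE 1.88), the immunoglobulin gene Iglc2 at -5.58 (SE 1.58) and Apol7c at -5.38 (SE 1.80). In KO on chow the SD of Glycam1 exceeded its mean (5.75 ± 8.48 CPM). Reads of these genes were highest in KO chow replicate 9 (lymphocyte score 6.1), with replicate 12 at a score of 4.3, and Cr2 was also at 11.1 CPM in replicate 11. Glycam1 had reads in only 1 of the 6 HFD libraries, so its fitted fold change depends on the prior count. Lymphocyte markers fell in 10 of 20 (18 over the list alone with 1 rise; median -3.76, set adjusted p = 0.00215, 0.605 with an estimated correlation; Ms4a1 -5.62, SE 1.66). As a covariate the lymphocyte score, the mean of this set, cannot test it. limma-voom called none of Glycam1 (0.075), Cr2 (0.154), Iglc2 (0.11), Apol7c (0.245) and Ms4a1 (0.137) at these adjusted p. The circadian clock fell in 8 of 17 (-0.41, set adjusted p = 0.0108, 0.435 with an estimated correlation). MondoA and ChREBP targets fell in 5 of 12 (-0.42, set adjusted p = 0.0132, 0.435 with an estimated correlation), among them Mlxipl (-1.18, SE 0.33, adjusted p = 0.0143) and Bhlhe40 (-1.61, SE 0.42). Gpam (-1.25, SE 0.28) and Lpin1 (-0.95, SE 0.18) fell within triglyceride and fatty acid cycling (9 of 27 fell and 2 rose, -0.31, set adjusted p = 0.031, 0.615 with an estimated correlation). Creatine cycling rose in 2 of 8 and fell in 2 (median 0.16, mean -0.76, adjusted p = 0.42), with the synthesis enzymes Gamt at 0.93 (SE 0.17) and Gatm at -0.77 (SE 0.24). Skeletal muscle markers fell in 13 of 22 (16 over the list alone; -2.66, set adjusted p = 0.00144, 0.533 with an estimated correlation), moving with Cacna1s (-3.75, SE 1.1) and Eno3 (-1.75, SE 0.44). Ucp1 fell by 4.40 (SE 1.48, adjusted p = 0.0329) and Mlx by 0.57 (SE 0.14, adjusted p = 0.00663). Arrdc4 (0.29), Txnip (-0.25) and Mlxip (-0.33) did not pass, though limma-voom (0.0291) and length offsets (0.0457) called Arrdc4. Ucp1 was not called by limma-voom (0.37), without a low-count filter (0.0639) or with only the 2 groups (0.0575), nor Gatm without the lymphocyte-rich libraries (0.116) or Apol7c with the lymphocyte score as a covariate (0.454). The calls of Ucp1, Apol7c, Gatm and Fdft1 (-0.99, SE 0.34) ended without 7, 7, 5 and 5 of the 24 libraries in turn (adjusted p up to 0.108, 0.198, 0.0793 and 0.156). Those of Cr2, Cacna1s and Mlxipl ended without KO chow replicates 9 (0.0559), 10 (0.0607) and 11 (0.0505). WT and KO shared 1469 rises (298 expected if independent) and 1426 falls (297 expected), with r = 0.738 across genes.

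**Figure D4:**
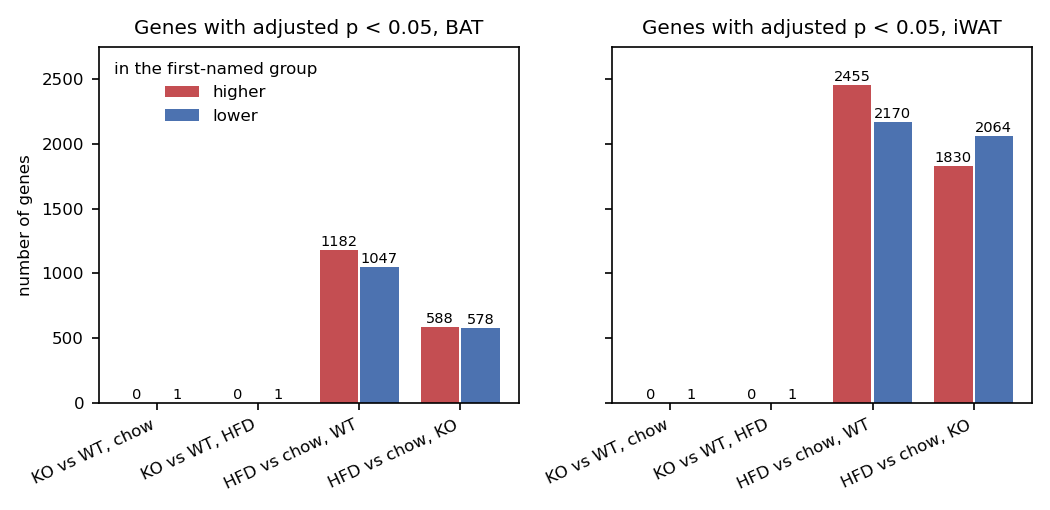
Number of genes called (adjusted p under 0.05, vertical axis, bars starting at 0) higher and lower in each comparison of each tissue. HFD changed 2229 and 1166 genes in WT and KO BAT and 4625 and 3894 in WT and KO iWAT, and deletion changed 1 gene on each diet in each tissue.

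The effects were then set against each other. Deletion shared Arrdc4 between diets and between tissues. The difference of its fold change between BAT and iWAT was -0.13 (SE 0.28) on chow and -0.81 (SE 0.28, unadjusted p = 0.00626, adjusted p = 1) on HFD. edgeR called 0 of 15800 genes for a difference of the deletion effect between tissues on either diet, with 322 genes on chow and 680 on HFD at unadjusted p under 0.05. HFD in WT shared 568 rises (199 expected) and 450 falls (165.4 expected) between BAT and iWAT, with r = 0.257 across genes. HFD in KO shared 233 (74.97 expected) and 220 (82.4 expected). Among the genes that HFD changed in WT BAT, 1701 of 2229 (76.3%) had a deletion effect on HFD of the opposite sign, and in iWAT 2729 of 4625 (59%). Both effects, and the choice of these genes, rested on the same WT HFD libraries, so these shares are biased toward opposite signs. Over all genes the correlation was -0.228 in BAT and -0.043 in iWAT, where simulated counts without any effect gave -0.49 and -0.501 from the shared libraries alone. When the WT HFD libraries were divided so that no library served both effects, the mean correlation was 0.028 in BAT (-0.253 to 0.484 over 6 divisions) and 0.04 in iWAT (-0.364 to 0.398 over 20 divisions). Genes are not independent replicates in any of these.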

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

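The tests of splits, of muscle and lymphocyte scores, of single libraries and of genes near Mlxip in this part were all chosen after the results were seen.

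Within groups, 26 of 320 values tested (8.1%) had a library far from the others by Dixon's criterion, and chance flags about 1 in 20 groups. In BAT (mean log2 CPM of a list, nearest library in brackets) these were in WT chow replicate 4 calcium cycling 3.5 (1.25), creatine cycling 4.16 (1.96) and skeletal muscle 5.89 (0.002). In WT chow replicate 1 fatty acid oxidation was 9.15 (9.4) and Mlxipl 9.09 (8.5), and in WT chow replicate 3 progenitor and fibroblast markers were 4 (3.77). KO chow replicate 6 had TCA cycle 9.93 (9.82), adipocyte markers 7.94 (7.42), Mlx 4.59 (4.86) and Mlxipl 8.61 (8.14), KO chow replicate 5 epithelial markers -0.826 (-0.489), and WT HFD replicate 9 TCA cycle 9.77 (9.63). In iWAT, WT chow replicate 4 had interferon response 5.34 (4.26), WT chow replicate 2 epithelial markers 3.9 (1.37), and KO chow replicate 11 cholesterol synthesis 5.79 (5.09) and interferon response 5.83 (4.07). WT HFD replicate 13 had creatine cycling 2.83 (2.52) and TCA cycle 7.38 (7.56), WT HFD replicate 16 lymphocyte markers 6.43 (1.83) and Lep 10.5 (11.5), and WT HFD replicate 17 blood markers 3.87 (4.21). KO HFD replicate 19 had calcium cycling 3.66 (2.92) and skeletal muscle 2.91 (1.13), KO HFD replicate 20 respiratory chain 7.21 (6.92) and epithelial markers 5.42 (0.258), and KO chow replicate 8 had Lep 11.5 (8.79).

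The effect of deletion differed between diets in 12 BAT sets by the interaction test, with medians of 0.25 for glycolysis (adjusted p = 0.00658), 0.15 for TCA cycle (0.00174), 0.10 for fatty acid oxidation (0.0344) and 0.17 for respiratory chain (4.64e-09). Medians were -0.61 for interferon response (3.28e-09), -0.75 for cell division (8.77e-05), -0.27 for extracellular matrix (0.000374) and -0.26 for progenitor and fibroblast markers (0.00313). They were -1.03 for macrophages (9.94e-17), -1.61 for lymphocytes (0.000204), 0.66 for epithelium (0.0259) and -0.36 for blood (0.000319). In iWAT 11 sets differed, with medians of 0.18 for branched-chain amino acid breakdown (0.000728), -0.25 for cholesterol synthesis (0.00504), -0.45 for immediate early genes (0.00317) and -0.24 for interferon response (0.0292). The others were -0.38 for cell division (0.00529), 0.41 for progenitor and fibroblast markers (0.00376), -0.38 for macrophages (0.00798), -2.81 for lymphocytes (0.00364), -0.27 for endothelium (0.0292), 3.37 for epithelium (0.000675) and 0.47 for blood (0.0205). Without the marker-rich libraries the BAT calls of lymphocytes (0.197), blood (0.0813) and epithelium (0.424) and the iWAT calls of cholesterol synthesis (0.0659) and endothelium (0.211) ended. With the marker covariate those of fatty acid oxidation in BAT (0.0511) and of interferon response and blood in iWAT (0.166 each) ended. With an estimated correlation the adjusted p ranged from 0.0932 to 0.848 in BAT and was 0.885 for each called iWAT set. Transcripts matched to no gene of the annotation, which no comparison used, also changed with HFD in WT, 8 of 215 in BAT (3 higher, 5 lower) and 43 of 244 in iWAT (18 higher, 25 lower).

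Other splits of the libraries were refitted to ask whether a count was larger than random groups of libraries give. For genes changed by HFD chance can be excluded in WT BAT (1 of 35 splits as large, the real one, with 2229 genes, highest other 1), KO BAT (1 of 35, 1166, highest other 1) and WT iWAT (1 of 100, 4625, highest other 2963). It is unlikely but not excluded in KO iWAT (2 of 100, 3894, highest other 4292). The split with 4292 genes exchanged KO chow replicate 8 and KO HFD replicate 20, and the one with 2963 WT chow replicate 5 and WT HFD replicate 16. Nor is chance excluded for KO against WT on HFD in iWAT (2 of 100 splits, 1 gene, highest other 1). For the number of genes, whichever they are, it cannot be excluded in BAT on chow (4 of 35; 1; highest other 4) or HFD (4 of 35; 1; highest other 905), in iWAT on chow (9 of 100; 1; highest other 1828), or for the average over diets (BAT 7 of 100; 2; highest other 581, and iWAT 6 of 100; 5; highest other 867). These numbers do not bear on the identity of the gene, and Arrdc4 was called in all 4 comparisons of KO with WT, which share no library (shared by the diets in BAT, 1 gene, 7.34e-05 expected). The interaction held 0 genes in both tissues, which all 100 splits reached (highest other 520 and 811). Splits with many genes point to a structure of the samples other than genotype. The BAT split with 905 genes set replicates 9, 10, 14 and 16, all rich in muscle markers, against the others on HFD, and the iWAT split with 1828 set 5 lymphocyte-rich libraries with KO replicate 11 against the others on chow. For counts of sets chance cannot be excluded in any comparison. In BAT as many sets came from 26 of 35 splits on chow (6 sets; highest other 15), 2 of 35 on HFD (16; 16), 6 of 35 for diet in WT (17; 19), 24 of 35 for diet in KO (10; 16) and 33 of 100 for the interaction (12; 24). In iWAT the same order gave 97 of 100 (7; 22), 11 of 100 (13; 16), 33 of 100 (17; 23), 8 of 100 (22; 24) and 79 of 100 (11; 21).

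The 1st pattern weighed is a cluster of genes near Mlxip. Averaged over diets, 7 of the 50 genes of lowest p in BAT (1.55 expected) and 13 of 50 in iWAT (1.5 expected) lay within 20 Mb of Mlxip. As many lay there in 3 of 100 splits (highest other 12) and 1 of 100 (highest other 10), so chance can be excluded in iWAT but not in BAT. In each tissue 0 other chromosomes had a stretch with as many (highest 4). An effect on adjacent genes alone is argued against in iWAT, where 11 of the genes lay 1 to 20 Mb away (1.38 expected), and stays open in BAT with 3 (1.42 expected). Sequence differences of another strain carried with the deleted allele are a candidate explanation, since of 11 such iWAT genes tested in BAT 7 had the same direction and an unadjusted p under 0.05, against 4 of 30 elsewhere (two-sided Fisher's exact p = 0.00308). It stays open, since direction alone was shared by 11 of 11 and 26 of 30, and among genes with p under 0.01 in a tissue by 29 of 33 near Mlxip and 281 of 388 elsewhere (Fisher's exact p = 0.0632).

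The 2nd pattern is the lower level of macrophage markers in KO BAT on HFD (median -0.82, adjusted p = 3.37e-19, and 0.248 with an estimated correlation, where the adjusted p below also rest on the preset correlation). Muscle RNA in some libraries is argued against, as the median was -0.82 with the muscle score as a covariate and -0.60 without the muscle-rich libraries (adjusted p = 2.18e-17 and 1.42e-10). So is a single library, as the highest adjusted p with 1 of 16 libraries left out was 4.49e-11 (lowest 1.65e-27). A larger share of adipocyte RNA that lowers all other cell types alike is argued against by endothelial markers, whose median was -0.14 against -0.82, where the SD of the macrophage members was 0.67. Chance cannot be excluded, since 2 of 35 splits gave as low a p (real 1.16e-20, the other 6.18e-22).

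The 3rd pattern is the lymphocyte signal of iWAT, for which 0 of 6 KO HFD libraries scored high. All 6 lymphocyte-rich libraries also had the 6 highest scores of 5 genes of lymph node vessels and stroma (lowest 3.66, highest of the others 2.57), so a piece of the inguinal lymph node in the dissected tissue is a candidate source. Without those libraries the KO against WT difference on HFD was a median of -0.41 (SE 0.5) for lymph node genes, 4 of 5 lower, and -0.84 for lymphocyte markers. Unequal amounts of lymph node and a difference of lymphocytes within the fat cannot be told apart, as the SE of the lymph node genes spans both.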

How the results depend on the processing

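The marker covariate and the exclusion of marker-rich libraries were chosen after the data were seen. No paired analysis was possible because replicate numbers are unique within a tissue, and most numbers shared by the tissues denote different genotypes or diets. Genes called, against all libraries and settings as reported, moved beyond 1.5 times in these cases, and the cause was not tested. KO against WT in BAT on chow (1) gave 2 with DESeq2, 0 with length offsets, 0 with only the 2 groups, 2 with the covariate and 0 without rich libraries. On HFD (1) the comparison gave 44 with DESeq2 (13 higher, 31 lower), 2 with limma-voom, 3 with the covariate and 0 without rich libraries. In iWAT DESeq2 gave 2 on chow (1), and on HFD (1) DESeq2 gave 17 and limma-voom 24. HFD in KO BAT (1166) gave 1810 with DESeq2, 670 with only the 2 groups and 100 without rich libraries. HFD in WT BAT (2229) gave 3864 with limma-voom and 668 without rich libraries, where fewer libraries were fitted. Deletion on chow and HFD shared in BAT (1 gene) gave 2 with the covariate, 2 with DESeq2 (Arrdc4 and Diablo) and 0 without rich libraries, with length offsets and with only the 2 groups. Deletion on chow shared by BAT and iWAT (1) gave 0 with length offsets, with only the 2 groups, without rich libraries and with limma-voom, each of which did not call Arrdc4 in BAT on chow. Deletion on HFD shared by both tissues (1) gave 2 with DESeq2 (Arrdc4 and Mlxip) and 0 without rich libraries. The correlation of diet and deletion effects on HFD was 0.028 with divided libraries and -0.496 with the covariate in BAT, and 0.04 and -0.293 in iWAT.

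With an estimated correlation 0 sets were called in each of the 10 comparisons. Set counts also moved for KO against WT in BAT on chow (6) to 3 with length offsets, in BAT on HFD (16) to 9 without rich libraries, in iWAT on HFD (13) to 4 with the covariate, and for the iWAT interaction (11) to 7 with the covariate. Direction turned, as adjusted p before and after, with the covariate for skeletal muscle in KO BAT diet (0.02, 0.54), lymphocytes (0.00121, 0.857) and cell division (0.979, 0.0167) in iWAT on chow. It also turned with the covariate for triglyceride cycling (0.0234, 0.958), respiratory chain (0.0315, 0.958) and cell division (0.00156, 0.902) in iWAT on HFD. Without rich libraries it turned for skeletal muscle in BAT on HFD (0.102, 1.42e-10) and cell division in the BAT interaction (8.77e-05, 0.724). In iWAT on chow it turned for cell division (0.979, 0.000113), lymphocytes (0.00121, 0.000583), extracellular matrix (0.947, 0.00518), skeletal muscle (0.947, 0.0209) and blood (0.000238, 0.6).

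Leaving out 1 library gave ranges of called genes of 1238 to 2380 for HFD in WT BAT (2229), 577 to 1347 in KO BAT (1166), 3595 to 5991 in WT iWAT and 2657 to 5471 in KO iWAT. For KO against WT they were 0 to 2 in BAT on chow (0 without KO replicate 5 or 7, 2 without KO HFD replicate 16) and 1 to 12 in BAT on HFD (12 without WT replicate 12, 9 without KO replicate 15, 2 without KO replicate 16). They were 1 to 6 in iWAT on HFD (6 without WT replicate 18, 2 without KO replicate 19) and 0 to 2 for the BAT interaction (2 without WT HFD replicate 12). Set counts ranged from 5 to 19 in iWAT on chow (7), from 5 to 18 in the iWAT interaction (11) and from 7 to 14 in iWAT on HFD (13). Sets that turned in direction had adjusted p from 0.0394 to 0.987 for lipogenesis in the BAT interaction (KO chow replicate 6), 5.27e-08 to 0.236 for skeletal muscle in BAT on chow and 0.000103 to 0.989 in the BAT interaction (both KO chow replicate 7). In iWAT on chow they were 3.52e-10 to 0.964 for respiratory chain (WT replicates 4 and 5, KO replicates 7 and 11), 7.95e-06 to 0.992 for TCA cycle (WT 5, KO 11), 0.00912 to 0.992 for branched-chain breakdown, 0.00345 to 0.988 for extracellular matrix (KO 8) and 0.0243 to 0.982 for skeletal muscle (KO 10). All for KO replicate 11, they were 0.00105 to 0.93 for lipogenesis, 0.0136 to 0.939 for glycolysis, 0.00448 to 0.908 for fatty acid oxidation and 6.37e-06 to 0.992 for interferon response. In the iWAT interaction they were 8.67e-07 to 0.393 for interferon response (KO chow 11) and 3.18e-05 to 0.785 for lymphocytes (WT HFD 16). For epithelium they were 0.000367 to 0.693 in KO against WT on HFD and 0.0301 to 0.849 for HFD in KO (KO HFD 20).

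Of calls of named genes with 1 library left out, 3706 kept their direction and side of the threshold, 94 were lost and 8 were gained, and of set calls 5404 kept both, 195 were lost, 181 were gained and 20 turned. With RLE size factors 186 of the named gene results kept both, with DESeq2 183 (3 gained), with library totals 181 (5 lost), without a filter 180 (6 lost), with limma-voom 170 (11 lost, 5 gained) and without rich libraries 141 (44 lost). With library totals the median of all genes was -0.11 for KO against WT on HFD in BAT (0.01 with TMM), -0.11 for the BAT interaction (0.01) and 0.10 for diet in WT BAT (0.00). It was 0.10 for diet in WT iWAT (-0.05), 0.07 for diet in KO iWAT (-0.05) and -0.10 for KO against WT on HFD in iWAT (-0.01).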

Other observations

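The comparison averaged over both diets in this part was chosen after the results were seen.

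In KO BAT on HFD a few genes outside macrophage and mitochondrial sets passed the test adjusted over their list alone. Slc2a1, the basal glucose transporter, was higher (0.62, SE 0.14, 0.00998 over the list alone, 0.283 over all genes), as was Gys1, glycogen synthase (0.36, SE 0.10, 0.0207 over the list alone). Ppp1r3b, a glycogen-targeting subunit of protein phosphatase, was lower (-0.60, SE 0.17, 0.0207 over the list alone). Glycogen metabolism as a set was not called (13 of 18 positive, median 0.21, adjusted p = 0.121). The interferon-induced Rsad2 was lower (-0.86, SE 0.21, 0.0156 over the list alone) and Pf4, a gene of platelets and their precursors, was lower (-0.89, SE 0.21, 0.00883 over the list alone).

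Averaged over both diets, Arrdc4 fell by 2.29 (SE 0.17) in BAT and by 1.82 (SE 0.12) in iWAT, and Hcrtr1, the orexin receptor gene (chromosome 4, 130130217 to 130139359), was higher in KO iWAT (1.63, SE 0.26, adjusted p = 0.00964). Diablo, a mitochondrial activator of apoptosis (chromosome 5, 123509765 to 123524176), was higher in KO BAT (0.62, SE 0.07, adjusted p = 0.00149). Adam1a (chromosome 5, 121518576 to 121545482; -0.88, SE 0.14, adjusted p = 0.00964) and Rplp0 (chromosome 5, 115559467 to 115563727; -0.73, SE 0.13, adjusted p = 0.0242) were lower in KO iWAT. At unadjusted p under 0.05 there were 854 genes in BAT and 1411 in iWAT in that comparison. In KO iWAT on chow Mmp12, a macrophage elastase (2.65, SE 0.72), and Ccl2, a chemokine that attracts monocytes (2.58, SE 0.75), both passed the test adjusted over the macrophage list alone (0.028) and not over all genes (0.989). KO SD lay above the mean (7.04 ± 9.29 CPM for Mmp12, 19 ± 36.2 CPM for Ccl2).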
